A study of Homo sapiens with 53 samples.

How the data were processed

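PolyA RNA from 32 colonic mucosa biopsies was sequenced by the submitters from TruSeq libraries, per the labels' protocols. The values used here are the raw counts per gene that the authors deposited in a single table of 23679 gene symbols and 32 libraries. GSNAP (a read aligner) and the hg19 genome build are named in the submitters' processing notes, without versions or roles. The counting tool, the gene annotation, the strand setting and any filter were not given in the sources used here. Without strand, reads of a gene and of its antisense partner cannot be told apart. Members of families with near copies (REG1A and REG1B, the PRSS1, PRSS2 and PRSS3P2 trypsin genes, HSPA1A and HSPA1B, and the CYP3A, UGT2B, GSTA and DEFA families) can share reads, so their separate values are uncertain. Gene symbols were used as deposited, and 20529 of them matched a current human symbol. The reference tables at hand were on another genome build, so no coordinates are printed. Chromatin accessibility samples (FAIRE, 12 colon-like and 9 ileum-like) were not analysed here.

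Groups were taken from the labels: 11 samples without inflammatory bowel disease (non-IBD), 11 Crohn's disease (CD) samples labelled colon-like and 10 labelled ileum-like. The labels do not state that each library came from another donor, so p-values measure the spread between these libraries. Sample numbers in the titles fall into a lower and a higher range, here called number series, which the labels do not explain. All 11 non-IBD libraries lay in the lower series, with 4 colon-like and 5 ileum-like libraries. The higher series held 7 colon-like and 5 ileum-like libraries. Replicate numbers are names in deposit order and pair nothing. No 2 libraries of a group agreed within sampling noise: the smallest chi-square per degree of freedom over gene counts was 12.6 in non-IBD, 45.6 in colon-like and 13.2 in ileum-like libraries.

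Y-linked and X-inactivation genes were left out before any test (105 genes). Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default filter by group (17064 genes tested) and robust quasi-likelihood fits of a single model over the 3 groups. Differences are log2 fold changes ± SE, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The all-CD comparison set the mean of both CD group means against the non-IBD mean. Gene levels are CPM, counts scaled by library total and TMM factor, given as mean ± SD. Simulated counts for the real genes (16835 tested) with known changes were analysed first. For ileum-like against non-IBD, 54.0% of genes simulated at 2-fold and 93.8% of those at 4-fold were called, with 5 of 16638 unchanged genes. For colon-like against non-IBD, 64.6% and 90.7% were called, with 8 of 16639 unchanged genes.

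Gene lists were written from textbook knowledge before the data were examined, as were the comparisons, the alternative settings and the rule for naming genes. Of 686 list entries, 672 matched a symbol in the table. The 13 mitochondrially encoded genes and MUC5AC did not, and 28 lists were tested. Some genes stand in several lists. Lists were tested with camera (limma 3.58.1) on voom values with a preset correlation between genes of 0.01, adjusted over the 28 lists within a comparison, and again with a correlation estimated per list. Counts of called members are over all genes tested, and counts "adjusted over the list alone" are given beside them. A score is the mean log2 CPM (prior count 2) of a list in a library. Scores were compared by two-sided permutation tests with 100000 resamples, whose smallest possible p is 1e-05, and by exact permutation tests within a number series. Their 95% intervals come from 10000 bootstrap resamples.

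The genes named are, per comparison, the 8 highest and 8 lowest log2 fold changes among called genes with an average log2 CPM of at least 2, leaving out immunoglobulin and T-cell receptor segments and uncharacterised or small RNA symbols. Added to these are the 3 members of each list with the smallest p, and APOA1 and CEACAM7 always. Some genes that this rule takes are not reported here. A fold against a group with 0 counts was computed against a floor of 3 counts over the group. Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

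Alternatives were other size factors, DESeq2 1.42.0, limma voom with quality weights, no filter and a stricter filter on low counts, a fit without robust dispersion, and stricter thresholds. Further alternatives were the number series or the pan-epithelial score as a term, fits within a series, fits of the compared groups alone, a single pooled CD group, and each library left out in turn. Colon-like libraries were also left out in turn from the values on Paneth cell genes. Chosen after the data were seen were fits without the 2 libraries that stood apart on the third principal component (11.2% of the variance), non-IBD replicate 6 and ileum-like replicate 10, and fits with all libraries thinned to the total of the shallowest. Up to 100 random splits of the libraries were refitted per comparison. Figures and score tests were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.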

Results

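Gene expression was measured in 32 biopsies of colonic mucosa that looked uninflamed to the eye. Of these, 11 came from donors without inflammatory bowel disease (non-IBD) and 21 from patients with Crohn's disease (CD), a chronic inflammation that can affect any part of the gut. The submitters had divided the CD samples into 2 molecular subtypes, 11 colon-like and 10 ileum-like, named after the colon and the last part of the small intestine. By the series title this is a molecular classification, so tests between the subtypes, and of a subtype against non-IBD, measure the size of the split and are not independent evidence for it. Summed counts per library ran from 2650864 to 71245557. Their median was 7851110 in non-IBD (range 2970167 to 45664893), 14729905 in colon-like (9713760 to 71245557) and 6380100 in ileum-like libraries (2650864 to 16008527). Ileum-like libraries were shallower than colon-like ones (mean 8898027 against 20179886, permutation p = 0.00938). The totals of all CD and non-IBD libraries did not differ past the threshold (mean 14807572 against 14225139, permutation p = 0.928).

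The first comparison asked how mucosa labelled ileum-like differs from non-IBD mucosa. Genes of the absorptive cells of the small intestine were far higher in the ileum-like libraries, and genes of the absorptive cells of the colon were far lower. FABP6, the ileal bile acid binding protein, had a mean of 2373 ± 1922 CPM in ileum-like (SD, n = 10) and 3.37 ± 4.56 in non-IBD libraries (SD, n = 11). CEACAM7, an adhesion protein of colonic epithelium, had 7.05 ± 8.30 CPM against 1301 ± 686. All 40 measured genes of the small-intestinal enterocyte list rose (median log2 fold change 6.25, camera adjusted p = 6.87e-71), and all 40 passed when adjusted over the list alone. APOA1 and APOA4, apolipoproteins of dietary fat export, rose by 8.99 ± 1.15 and 8.98 ± 1.24 on the log2 scale (edgeR adjusted p = 2.4e-07 and 1.04e-06). The glucose transporter SLC5A1 rose by 5.22 ± 0.31. The enterocyte score was 8.41 ± 0.55 (SD, n = 10) in ileum-like and 2.07 ± 0.67 (SD, n = 11) in non-IBD libraries, a difference of 6.33 (95% interval 5.83 to 6.84, permutation p = 1e-05, the smallest possible).

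Of 29 measured colonocyte genes, 23 fell, 1 rose and 5 did not pass (median -3.11, camera adjusted p = 1.79e-21; 25 lower and 2 higher when adjusted over the list alone). Among the lowest were MS4A12 (-8.09 ± 0.67), the water channel AQP8 (-7.63 ± 0.87), CEACAM7 (-7.59 ± 0.66) and CA2, a carbonic anhydrase (-7.06 ± 0.48). The colonocyte score was 3.82 ± 0.56 in ileum-like (SD, n = 10) against 7.26 ± 0.48 in non-IBD libraries (SD, n = 11), a difference of -3.44 (95% interval -3.88 to -3.02, permutation p = 1e-05). Of the HOX paralogs 9 to 13, which mark position toward the rear end of the gut, 8 of 9 fell and 1 did not pass (median -4.82, camera adjusted p = 3.62e-08; all 9 lower when adjusted over the list alone). HOXA13 fell by 7.59 ± 0.98. HOXD10 had 0 counts over the 10 ileum-like libraries and 874 over the non-IBD libraries, which makes it at least 156-fold lower at a floor of 3 counts over the group. HOXD11 had 2 counts, 164-fold lower with a counting interval of 45.1 to 1350. With HOXD10 at its bound the list's median was also -4.82. Of 19 HOX paralogs 2 to 8, 3 rose and 8 fell (median -0.59, camera adjusted p = 0.326). The risers were HOXC8 (5.29 ± 0.67), HOXC6 (3.71 ± 0.66) and HOXC4 (2.34 ± 0.43).

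**Figure D1:**
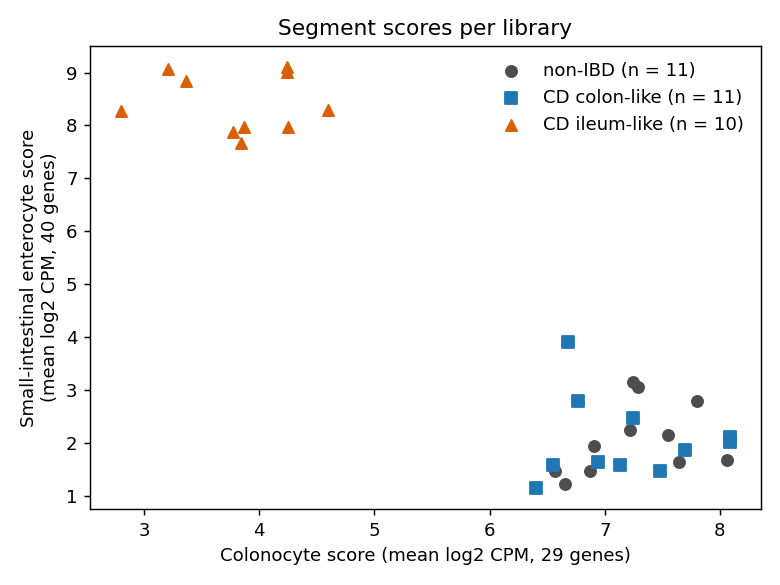
Small-intestinal enterocyte score against colonocyte score, each the mean log2 CPM of its list, with a point per library (11 non-IBD, 11 colon-like CD, 10 ileum-like CD). The ileum-like libraries have enterocyte scores of 7.66 to 9.11 and colonocyte scores of 2.80 to 4.60, outside the ranges of the other 22 libraries (1.14 to 3.91 and 6.40 to 8.09).

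Lists of transport and metabolic genes also moved. The bile acid and lipid transport list shares genes such as FABP6 and APOA1 with the enterocyte list. The ion and water transport list shares genes such as AQP8 and CA2 with the colonocyte list, so neither is separate evidence from the segment markers. In bile acid and lipid transport, 23 of 32 genes rose and 1 fell (median 2.58, camera adjusted p = 2.77e-23; 23 higher and 2 lower adjusted over the list alone), among them the export pump ABCC2 (6.06 ± 0.32) and the sterol transporter ABCG8 (6.14 ± 0.51). In xenobiotic metabolism, 29 of 36 rose and 1 fell (median 1.72, camera adjusted p = 1.82e-24; 30 and 1 adjusted over the list alone), with GSTA2, a glutathione transferase, at 6.95 ± 0.50. In ion and water transport, 17 of 29 fell and 5 rose (median -1.74, camera adjusted p = 3.94e-07; adjusted p = 0.117 with an estimated correlation; 19 lower and 5 higher adjusted over the list alone). Of 19 small-intestinal transcription factors, 9 rose and 3 fell (median 0.62, camera adjusted p = 0.00297; adjusted p = 0.234 with an estimated correlation; the same counts adjusted over the list alone). CREB3L3 (6.74 ± 0.62) and HNF4G (2.37 ± 0.23) rose. Among 19 tight junction genes, 4 rose and 3 fell (median 0.06, camera adjusted p = 0.249). The pore-forming claudins CLDN2 (5.73 ± 0.57) and CLDN15 (3.49 ± 0.29) rose, and CLDN8 fell by 6.18 ± 1.09.

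Secretory and immune genes also differed. Of 14 Paneth cell and regenerating protein genes, 13 rose and 1 did not pass (median 6.74, camera adjusted p = 2.13e-15; 13 adjusted over the list alone). DEFA5, a defensin of Paneth cells, had 3698 ± 1706 CPM in ileum-like and 21.4 ± 42.3 in non-IBD libraries (9.09 ± 12.2 without non-IBD replicate 3), and the antimicrobial lectin REG3G rose by 7.65 ± 0.96. Of 20 goblet cell genes, 6 fell and 14 did not pass (median -0.55, camera adjusted p = 0.00297; adjusted p = 0.473 with an estimated correlation), led by the mucin MUC5B (-4.83 ± 0.67). Of 17 enteroendocrine genes 5 rose and 12 did not pass (median 0.23, camera adjusted p = 0.00186; adjusted p = 0.26 with an estimated correlation), with the ileal hormone gene NTS at 7.87 ± 0.71. In interferon response and antigen presentation, 30 of 35 genes rose (median 1.37, camera adjusted p = 9.86e-13; adjusted p = 0.176 with an estimated correlation; 31 adjusted over the list alone), among them the peptide transporter TAP2 (1.55 ± 0.21) and CD74 (1.68 ± 0.29). Of 27 T and NK cell genes, 15 rose (median 1.18, camera adjusted p = 1.62e-06; adjusted p = 0.459 with an estimated correlation), including CD8B (2.27 ± 0.41). In neutrophil and acute inflammation, 7 of 33 rose (median 0.86, camera adjusted p = 0.00297; adjusted p = 0.661 with an estimated correlation), led by the chemokine CXCL6 (4.43 ± 0.50) and DMBT1, a mucosal scavenger protein (4.97 ± 0.80). Of 23 macrophage and dendritic cell genes 5 rose (median 0.69, camera adjusted p = 0.00602; adjusted p = 0.625 with an estimated correlation), with CD68 at 1.57 ± 0.21. Adjusted over the list alone, 6 goblet cell genes were lower, 6 enteroendocrine, 17 T and NK cell and 7 neutrophil genes were higher, and 8 macrophage and dendritic cell genes were higher and 1 lower.

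In all, 3656 of 17064 genes were called in this comparison, 1863 higher and 1793 lower. At an absolute log2 fold change of at least 1 the count was 1775, and at an adjusted p under 0.01 it was 2237. All non-IBD libraries belong to the lower number series. Within that series 2719 genes were called, with 5 ileum-like libraries.

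**Figure D2:**
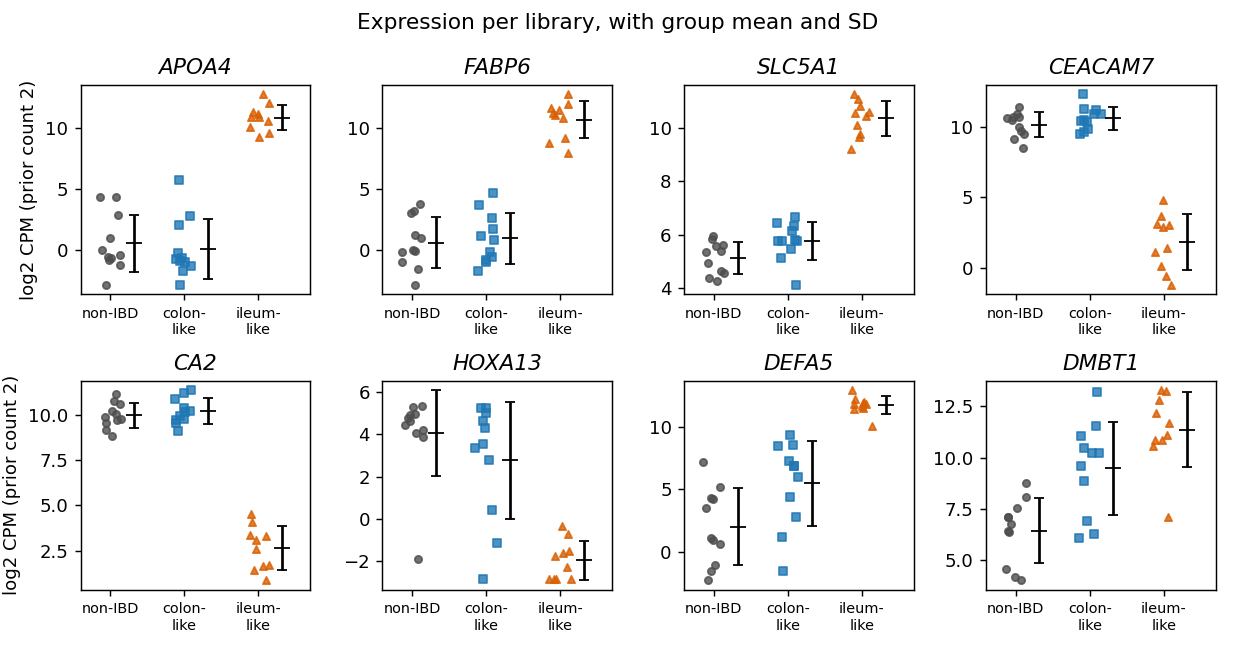
Log2 CPM (prior count 2) of 8 genes, with a point per library by group (11 non-IBD, 11 colon-like CD, 10 ileum-like CD), and bars for group mean and SD. APOA4, FABP6 and SLC5A1 are higher, and CEACAM7, CA2 and HOXA13 lower, in the mean of the ileum-like libraries, and DEFA5 in colon-like libraries spans -1.54 to 9.36.

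The next comparison set the 2 CD subtypes against each other. Segment markers also separated these groups. The enterocyte score was 8.41 ± 0.55 in ileum-like (SD, n = 10) and 2.05 ± 0.77 in colon-like libraries (SD, n = 11), a difference of 6.36 (95% interval 5.78 to 6.89, permutation p = 1e-05). Within the lower number series it was 5.93, and within the higher series 6.50. The colonocyte score was 3.82 ± 0.56 against 7.19 ± 0.59, a difference of -3.37 (95% interval -3.85 to -2.91, permutation p = 1e-05). All 40 enterocyte genes were higher (median 6.26, camera adjusted p = 1.53e-78). TMPRSS15, the enteropeptidase that activates trypsinogen (9.01 ± 0.56), FABP6 (8.96 ± 1.01) and the ileal bile acid transporter SLC10A2 (8.47 ± 0.95) were among the highest genes. Of the colonocyte genes 24 were lower, 2 higher and 3 did not pass (median -3.33, camera adjusted p = 2.57e-22), with MS4A12 (-8.42 ± 0.68), AQP8 (-8.36 ± 0.89) and CEACAM7 (-8.06 ± 0.67) lowest. Of the HOX paralogs 9 to 13, 8 of 9 were lower (median -3.87, camera adjusted p = 2.73e-07). HOXD10 was at least 81.9-fold lower and HOXD11 was 65.5-fold lower (counting interval 18 to 543). Adjusted over the list alone, the counts were 40 higher for enterocyte genes, 25 lower and 3 higher for colonocyte genes, and 9 lower for the HOX paralogs.

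Bile acid and lipid transport (22 higher, 3 lower of 32, camera adjusted p = 2.48e-22), xenobiotic metabolism (27 higher, 2 lower of 36, camera adjusted p = 2.91e-24) and Paneth cell genes (12 of 14 higher, median 3.99, camera adjusted p = 2.88e-13) were again higher. Enteroendocrine genes were higher in 10 of 17 (median 1.25, camera adjusted p = 1.8e-07), led by NTS (6.22 ± 0.63) and somatostatin SST (2.91 ± 0.49). These 4 lists also passed with an estimated correlation, as did the enterocyte, colonocyte and HOX 9 to 13 lists. Ion and water transport genes were lower in 18 and higher in 3 of 29 (median -1.66, camera adjusted p = 7.77e-09; adjusted p = 0.0505 with an estimated correlation). Goblet cell genes were lower in 7 and higher in 1 of 20 (median -0.52, camera adjusted p = 0.000646; adjusted p = 0.414 with an estimated correlation), with MUC5B at -5.22 ± 0.69 and MUC4 at -3.88 ± 0.50. Genes of mitochondrial respiration were lower in 12 of 33 and 17 adjusted over the list alone (median -0.39, camera adjusted p = 2.15e-05; adjusted p = 0.555 with an estimated correlation). Small-intestinal transcription factors were higher in 9 and lower in 3 of 19 (camera adjusted p = 0.00385; adjusted p = 0.265 with an estimated correlation), with MAF at 2.92 ± 0.24. Interferon response and antigen presentation genes were higher in 6 and lower in 2 of 35 (median 0.49, camera adjusted p = 0.000541; adjusted p = 0.624 with an estimated correlation). T and NK cell genes were higher in 5 of 27 (median 0.75, camera adjusted p = 3.03e-05; adjusted p = 0.555 with an estimated correlation). Lists called at larger p-values were macrophage and dendritic cell (median 0.14, camera adjusted p = 0.0366), fibroblast (0.32, 0.0256), endothelial (0.40, 0.0311) and mast cell (0.44, 0.0405), all up. The pan-epithelial list was called down (median -0.29, camera adjusted p = 0.0306). No single endothelial or mast cell gene passed. With an estimated correlation the adjusted p was 0.624 for mast cells and 0.658 for the other 4. Adjusted over the list alone, higher and lower counts were 24 and 3 for bile acid and lipid transport, 28 and 2 for xenobiotic metabolism, 6 and 19 for ion and water transport, and 12 and 0 for Paneth cell genes. They were 13 and 0 for enteroendocrine, 1 and 8 for goblet cell, 9 and 4 for transcription factor, 7 and 2 for interferon, and 5 and 0 for T and NK cell genes. In all, 3086 genes were called, 1506 higher and 1580 lower in ileum-like libraries. The count was 1336 within the lower series (5 against 4 libraries) and 1032 within the higher series (5 against 7).

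Whether the subtype difference depended on the number series was tested as an interaction: edgeR called 0 of 16785 genes, with 264 at an unadjusted p under 0.05, and DESeq2 called 0, with 380. The 0 calls do not show equal differences in both series. Estimated interactions were large for several enterocyte genes, on the log2 scale 4.76 for APOA4, 4.46 for APOA1, 3.82 for FABP6 and -4.42 for LCT (edgeR adjusted p = 1), with 4 to 7 libraries per subtype and series. The APOA4 value rests largely on low colon-like levels. Their log2 CPM was -2.85 to -0.70 in the higher series and -0.28 to 5.72 in the lower, highest in replicate 11. Ileum-like levels overlapped, at 9.25 to 11.28 in the higher and 10.07 to 12.75 in the lower series.

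Colon-like CD mucosa was compared with non-IBD mucosa to ask how CD mucosa with the colonic profile differs from mucosa without the disease. The enterocyte and colonocyte scores did not differ past the threshold, and the HOX 9 to 13 score was lower in colon-like libraries before adjustment. The enterocyte score differed by -0.02 (95% interval -0.58 to 0.58, permutation p = 0.945), the colonocyte score by -0.07 (-0.50 to 0.37, permutation p = 0.765) and the HOX 9 to 13 score by -0.74 (-1.26 to -0.17, permutation p = 0.0212, adjusted p = 0.066 over 84 list and group tests). No gene passed in edgeR: 0 of 17064 were called, with 1109 at an unadjusted p under 0.05, 578 of these higher in colon-like libraries, and a smallest adjusted p of 0.149. The unadjusted count was 1966 without colon-like replicate 5, 2081 without the 2 libraries apart on the third principal component, 533 with the number series as a term, 560 within the lower series and 3186 in limma voom. Without non-IBD replicate 6, 1003 were higher. DESeq2 called 32 and limma voom with quality weights 129, and leaving out colon-like replicate 5 gave 36 in edgeR and leaving out colon-like replicate 7 gave 8. The members of several lists nevertheless shifted together in the camera test, which called 10 of 28 lists. None of these calls held with an estimated correlation. Of the called lists' scores per library, only the Paneth cell score passed in permutation tests adjusted over the 84 list and group tests (adjusted p = 0.0403). The adjusted p was 0.103 for interferon response and antigen presentation, 0.113 for enteric glia and neurons, and 0.158 to 0.579 for the remaining called lists. The 84 tests include ileum-like comparisons whose small p-values the molecular labels build in, which loosens this adjustment. Among the 28 colon-like tests alone the Paneth cell score would not pass.

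The 4 lists higher in colon-like libraries were those of interferon response and antigen presentation, Paneth cells, neutrophils and mitochondrial respiration. All 35 interferon response and antigen presentation genes had positive log2 fold changes (median 0.81, camera adjusted p = 3.13e-18; adjusted p = 0.351 with an estimated correlation), and 24 were higher when adjusted over the list alone. IFI27 had 283 ± 142 CPM in colon-like (SD, n = 11) and 110 ± 47.8 in non-IBD libraries (1.36 ± 0.29, edgeR adjusted p = 0.149), and TAP1 had 156 ± 69.6 against 74.6 ± 21.8 (1.07 ± 0.24, edgeR adjusted p = 0.149). Of 14 Paneth cell and regenerating protein genes 13 were positive (median 2.50, camera adjusted p = 3.28e-07; adjusted p = 0.351 with an estimated correlation), and 10 were higher when adjusted over the list alone. DEFA5 had 168 ± 207 CPM against 21.4 ± 42.3, and REG3A, a lectin against bacteria, 122 ± 146 against 10.8 ± 19.5 (edgeR adjusted p = 0.276). Without non-IBD replicate 3 the non-IBD means were 9.09 ± 12.2 and 5.28 ± 7.04 (SD, n = 10). HOXB13, a marker of the lower colon, had 5.05 ± 16.2 CPM in colon-like and 48.1 ± 59.4 in non-IBD libraries (-3.23 ± 1.14, edgeR adjusted p = 0.543). That colon-like mean rests on replicate 5, at 53.7 CPM, and without it was 0.18 ± 0.184 (SD, n = 10). The Paneth score difference of 1.70 was 0.85 with HOXB13 as a term, and without replicate 5 it was 2.03, of which 73.7% remained with that term. Of 33 neutrophil and acute inflammation genes 23 were positive (median 0.49, camera adjusted p = 5.35e-06; adjusted p = 0.619 with an estimated correlation), with 9 higher and 1 lower when adjusted over the list alone. DMBT1 had 1796 ± 2677 CPM (1036 ± 947 without colon-like replicate 3) against 135 ± 124 (3.73 ± 0.75, edgeR adjusted p = 0.149; DESeq2 adjusted p = 0.000263), and CXCL5, a chemokine for neutrophils, had a log2 fold change of 3.52 ± 0.90. Nuclear genes of mitochondrial respiration were positive in 31 of 33 by a small amount (median 0.17, camera adjusted p = 8.18e-05; adjusted p = 0.721 with an estimated correlation), with 0 passing when adjusted over the list alone.

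The 6 lists lower in colon-like libraries were those of enteric glia and neurons, enteroendocrine cells, smooth muscle, fibroblasts, mast cells and eosinophils, and endothelial cells. Enteric glia and neuron genes were negative in 13 of 14 (median -0.61, camera adjusted p = 3.28e-07; adjusted p = 0.41 with an estimated correlation), and enteroendocrine genes in 14 of 17 (median -0.74, camera adjusted p = 0.000394; adjusted p = 0.41 with an estimated correlation). TPH1, which makes serotonin, had 14.9 ± 6.28 CPM against 29.0 ± 20.2 (-0.97 ± 0.33, edgeR adjusted p = 0.492). Smooth muscle (median -0.45, camera adjusted p = 5.35e-06; adjusted p = 0.619 with an estimated correlation), fibroblast and matrix (median -0.29, camera adjusted p = 0.00015; adjusted p = 0.671 with an estimated correlation), mast cell and eosinophil (median -0.20, camera adjusted p = 0.0047; adjusted p = 0.619 with an estimated correlation) and endothelial genes (median -0.36, camera adjusted p = 0.0105; adjusted p = 0.775 with an estimated correlation) were lower as lists. Adjusted over the list alone, 6 enteroendocrine genes were lower and 1 higher, 1 fibroblast gene was higher and no gene of the other 4 lists passed. Smooth muscle scores were 9.68, 9.77 and 8.92 in non-IBD replicates 1, 4 and 9, and 5.51 to 6.94 in the other non-IBD libraries. They were 10.32 and 8.65 in colon-like replicates 5 and 11, and 4.25 to 5.92 in the other colon-like libraries. The same libraries had the highest enteric glia and neuron scores of their groups, so both lists depend on a few libraries. The remaining 18 lists were not called. Among them, the enterocyte list had a positive median of 0.11 beside a negative camera direction (camera adjusted p = 0.583). The colonocyte list had a median of 0.13, a mean of -0.03 and a positive camera direction (camera adjusted p = 0.753).

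**Figure D3:**
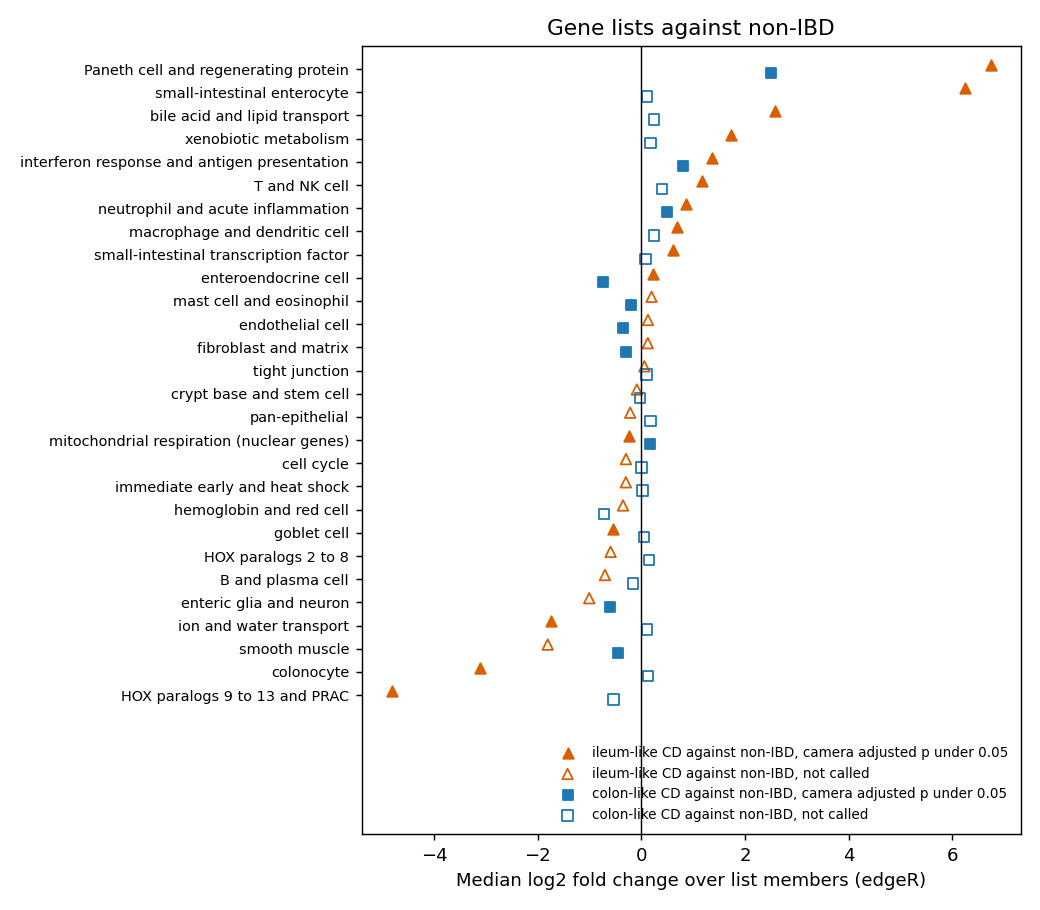
Median log2 fold change (edgeR) of each of the 28 gene lists for ileum-like CD (triangles) and colon-like CD (squares) against non-IBD. Filled symbols mark lists with a camera adjusted p under 0.05 at the preset correlation, 15 for ileum-like and 10 for colon-like CD, of which 6 and 0 held with an estimated correlation.

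All CD libraries were then set against non-IBD, giving both subtypes equal weight. Genes of the Paneth cell and enterocyte lists rose, and genes of the HOX 9 to 13 and colonocyte lists fell. REG1B (6.43 ± 1.19), REG3A (5.77 ± 0.99), DEFA6 (5.57 ± 0.97) and the dipeptidase DPEP1 (5.20 ± 0.52) rose, with edgeR adjusted p-values of 0.000318, 0.000111, 0.000137 and 1.7e-08. HOXB13 (-5.17 ± 1.05), CLDN8 (-4.22 ± 0.72) and HOXA13 (-4.06 ± 0.62) fell. Of the Paneth cell list 12 of 14 rose (median 4.73, camera adjusted p = 2.43e-15). Interferon and antigen presentation genes rose in 26 of 35, and 32 adjusted over the list alone (median 1.03, camera adjusted p = 3.96e-18; adjusted p = 0.0785 with an estimated correlation), with TAP1 at 1.22 ± 0.22. DMBT1 (4.35 ± 0.74), CXCL6 (3.11 ± 0.45) and the nitric oxide synthase NOS2 (2.44 ± 0.54) rose among the 6 of 33 neutrophil and acute inflammation genes that passed (camera adjusted p = 0.000108; adjusted p = 0.511 with an estimated correlation). Enterocyte genes rose in 38 of 40 (median 3.05, camera adjusted p = 7.33e-54) and colonocyte genes fell in 18 of 29 (median -1.43, camera adjusted p = 5.14e-21). These 2 shifts came from the ileum-like libraries, since the medians were 6.25 and -3.11 there and 0.11 and 0.13 in colon-like libraries. Of the HOX 9 to 13 genes 6 of 9 fell (median -2.455, camera adjusted p = 7.07e-10). Their median was -4.82 in ileum-like libraries and -0.53 in colon-like libraries, where 0 of 9 passed (camera adjusted p = 0.104). Smooth muscle genes (median -1.03, 0 of 14 passed, camera adjusted p = 0.00425; adjusted p = 0.673 with an estimated correlation) and enteric glia and neuron genes (median -0.80, 2 of 14 fell, camera adjusted p = 0.001; adjusted p = 0.511 with an estimated correlation) were lower as lists. The non-IBD smooth muscle level rests largely on replicates 1, 4 and 9, with scores of 8.92 to 9.77. The other non-IBD libraries had 5.51 to 6.94, and the ileum-like libraries 5.63 to 7.21. Adjusted over the list alone, 40 enterocyte and 12 Paneth cell genes were higher, 21 colonocyte genes were lower, and of the neutrophil list 8 were higher and 1 lower. In all, 1519 genes were called, 885 higher and 634 lower, and with all CD libraries as a single group 647, 536 of them higher. That single group ended 27 of the 69 calls among genes named for this comparison, among them CA1, CA2, CEACAM7, MS4A12, HOXA13 and HOXD10. With the number series as a term 929 genes were called.

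Sharing between the subtypes was examined last, since both comparisons used the same non-IBD libraries. No gene was called in the same direction in both in edgeR, which follows from the 0 calls for colon-like libraries. At an unadjusted p under 0.05, 304 genes were higher and 212 lower in both. These counts were 543 and 308 without non-IBD replicate 6, where independent lists of the same sizes would share 177.2 and 124.5. They were 417 and 496 without colon-like replicate 5 (independent lists 127.9 and 208.6). With the number series as a term they were 225 and 118 (independent lists 43.2 and 35.2). For the 304 and 212 of the main fit, independent lists of the same sizes would share 89.2 and 94.2. Simulated unchanged groups against the same controls shared 85.1 and 63.6 on average. With the controls split at random between the comparisons the averages were 170 and 97.9. The simulation left both CD groups unchanged, while 5660 genes had an unadjusted p under 0.05 for the real ileum-like libraries. A changed ileum-like group beside an unchanged colon-like group was not simulated. The simulated values here and below therefore do not show how much sharing the common controls alone would give. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.331, against 0.486 for simulated unchanged groups and 0.16 with split controls (0.0284 to 0.257 over 20 splits). Their covariance was 0.112, against 0.041 for unchanged groups, a difference of 0.0713, and 0.0646 with split controls. Log2 fold changes had the same sign in 63.7% of genes, against 66.2% for unchanged groups. DESeq2 shared 24 calls and limma voom 87.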

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

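The tests in this part were fixed before the data were examined, and the measures in which they were run follow the naming rule and the fixed lists. In the 10 ileum-like libraries, the gap between the extreme library and its nearest neighbour was divided by the whole range of the group and compared with Dixon's 95% critical value for 10 samples. Groups of 11 libraries were not tested. Of 161 measures, 16 passed, where chance alone passes about 1 in 20, and measures of related genes are not independent.

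Ileum-like replicate 8, the shallowest library at 2650864 counts, was the lowest in 12 of the 16. Its Paneth cell and regenerating protein score was 5.77 against 7.27 in the next library (ratio 0.557). The defensin DEFA5 was at a log2 CPM of 10.05 against 11.39 (0.470), and the trypsin genes PRSS1 (2.35 against 4.66, 0.540), PRSS2 (2.60 against 4.16, 0.470) and PRSS3P2 (3.28 against 5.03, 0.492) were lowest too. So were DMBT1 (7.11 against 10.56, 0.557), the crypt gene OLFM4 (8.14 against 10.45, 0.525) and the macrophage receptor CSF1R (5.16 against 6.27, 0.478). Its mitochondrial respiration genes were low as well: UQCRFS1 (4.96 against 6.11, 0.644), COX5B (5.96 against 6.73, 0.548), ATP5G1 (3.70 against 5.09, 0.507) and UQCRC1 (6.23 against 7.25, 0.502).

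Ileum-like replicate 1 had the highest interferon response and antigen presentation score, 7.30 against 6.33 in the next library (0.535), and the lowest SOX10, a glial gene, at -2.85, the value of a count of 0, against -0.50 (0.469). GZMA, a granzyme of T and NK cells, was lowest in ileum-like replicate 9 (3.24 against 4.30, 0.527). HSPB1, a small heat shock protein, was highest in ileum-like replicate 10 (5.80 against 4.65, 0.538).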

How the results depend on the processing

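Chosen after the data were seen were the fits with thinned libraries and those without the 2 libraries apart on the third principal component; the other alternatives were planned. No result changed direction past a threshold. The 4 score differences of ileum-like libraries kept their direction and call throughout. For ileum-like against non-IBD (3656 genes) the count fell to 2237 at an adjusted p under 0.01 and 1775 with the 2-fold limit. For colon-like against non-IBD (0) DESeq2 gave 32, voom with quality weights 129 and no filter 1, and leaving out each library in turn 0 to 36 (36 without colon-like replicate 5, 8 without colon-like replicate 7, 0 without any other). For ileum-like against colon-like (3086) the count was 1336 in the lower and 1032 in the higher number series, which hold fewer samples, 1958 at an adjusted p under 0.01 and 1540 with the 2-fold limit. For all CD (1519) it was 2877 with voom, 929 with the series term, 2314 with the pan-epithelial term, 647 with a single CD group, 811 at an adjusted p under 0.01 and 692 with the 2-fold limit. Calls shared by both subtypes (0) were 24 in DESeq2, 87 in voom and 1 without a filter, and 0 to 27 leaving out each library (27 without colon-like replicate 5, 7 without colon-like replicate 7). With an estimated correlation the called lists fell from 15 to 6, 10 to 0, 18 to 7 and 15 to 6 (ileum-like, colon-like, between subtypes, all CD). The enterocyte score of colon-like minus non-IBD, -0.02, was 0.63 within the lower series (exact permutation p = 0.172), -0.298 as a median over the list (p = 0.444), -0.155 with the pan-epithelial score subtracted (p = 0.656) and -0.207 to 0.086 leaving out each library, and the colonocyte score, -0.07, was -0.348 within the lower series (exact permutation p = 0.197), -0.202 with the pan-epithelial score subtracted (p = 0.131) and -0.159 to 0.012 leaving out each library. Apart from the thresholds, the smaller series and the estimated correlation, the cause was not tested. Other counts were within 1.5 times the reported value, such as 2988, 0, 2506 and 1245 thinned and 3935, 0, 3242 and 1986 without the 2 libraries apart. No scaling moved the share of higher calls by over 10 points. Of 223 called results on named genes 69 lost the call somewhere (288 of 9837 values: 167 of 7120 leaving out a library, 33 of 223 in the lower and 21 of 75 in the higher series, 27 of 69 with a single CD group), and 0 reversed. Of 65 uncalled results 68 of 2845 values passed. The shallowest library has 2650864 counts. Simulated 2-fold changes were called in only 54.0% (ileum-like) and 64.6% (colon-like) of genes, so counts can leave out changes of that size. The simulation changed far fewer genes than the 3656 called for ileum-like libraries, which makes its adjusted threshold stricter. The 54.0% therefore does not measure the share of real 2-fold changes called there.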

Other observations

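Tests chosen after the result was seen were those of a site within the span of the other biopsies, of colonic tissue in ileum-like biopsies, of depth in 2 comparisons, of biopsies taken from ileum, and all 3 on Paneth cell genes in colon-like libraries with the values leaving out a library; the splits and the tests of epithelial share, number series, biopsy position and library size were written before. In the immediate early and heat shock list 6 of 21 genes were lower in ileum-like than colon-like libraries and 15 did not pass (median -0.26, camera adjusted p = 0.0534). The near-identical chaperone genes HSPA1A (-2.59 ± 0.50) and HSPA1B (-2.53 ± 0.48) and their partner DNAJB1 (-1.63 ± 0.37) led them, calls that were lost within the higher number series. HSPA1A averaged 428 ± 595 CPM in colon-like, 145 ± 64.7 in non-IBD and 70.8 ± 33 in ileum-like libraries. Against non-IBD, 2 of the 21 fell in ileum-like libraries (camera adjusted p = 0.1). The matrix protein gene POSTN fell by 3.27 ± 0.43 in ileum-like libraries against non-IBD, while MMP3, a matrix protease, rose by 3.82 ± 0.86, and the fibroblast and matrix list as a whole had 5 higher and 2 lower of 32 (camera adjusted p = 0.656).

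The camera test did not call several lists for ileum-like against non-IBD libraries. Cell cycle genes had 0 of 28 called (camera adjusted p = 0.1), endothelial genes 0 of 17 (0.394), crypt base and stem cell genes 2 higher and 2 lower of 18 (0.985) and pan-epithelial genes 2 higher and 4 lower of 20 (0.208). B and plasma cell genes had 2 lower of 20 (0.113), mast cell and eosinophil genes 1 higher of 13 (0.565), smooth muscle genes 4 lower of 14 (0.1; 9 lower adjusted over the list alone) and enteric glia and neuron genes 4 lower of 14 (0.0888). The enteric glia and neuron score was nevertheless lower by 0.78 (95% interval of the difference -1.33 to -0.23, adjusted p = 0.0498 over 84 list and group tests). Those 84 tests hold many small p-values that the molecular labels build in, which loosens this adjustment. In the hemoglobin and red cell list 1 of 6 fell (0.581), and it was CA1, which colonocytes also express. Camera did call the nuclear genes of mitochondrial respiration, with 3 lower of 33 (camera adjusted p = 0.0261; adjusted p = 0.8 with an estimated correlation). Between the subtypes, smooth muscle genes had a median of -1.17 and enteric glia and neuron genes of -0.41, beside positive camera directions (camera adjusted p = 0.718 and 0.748). Smooth muscle scores were far above the rest of their group in non-IBD replicates 1, 4 and 9 and in colon-like replicates 5 and 11. The smooth muscle values of ileum-like libraries against either group therefore depend on those libraries.

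The first pattern is the split of CD samples into ileum-like and colon-like libraries: of 100 splits of the same libraries 1, the real one, gave as many genes (3086, highest other 14), which is no test of chance, since labels drawn from molecular profiles build in a large difference. Epithelial share does not account for it, since the enterocyte score differed by 6.72 and the colonocyte score by -3.01 after the pan-epithelial score was subtracted, and neither does the number series (5.93 within the lower, 6.50 within the higher) nor depth (2334 of the 3086 calls remained after thinning). In all 10 ileum-like libraries 6 of 29 colonocyte genes lay under 5% of their non-IBD level. This argues against a large part of colonic tissue that kept its colonocyte transcripts in each biopsy. It says nothing of colonic tissue that had lost those transcripts. The count replaced a first test that decided nothing, in which summed HOX 9 to 13 levels were 17.9% of non-IBD (95% interval 10.5 to 27.4). HOX 9 to 13 genes fell as a set (median -3.87), yet 0 of 10 ileum-like libraries lay inside the range of the other 22 in HOX and colonocyte scores, while 10 of 10 lay outside it in all 3 segment scores, a distance that labels drawn from molecular profiles build in. Biopsies taken from ileum cannot be told apart from a change of epithelial identity in the colon, which the label of colonic tissue would need. Both predict the direction of the enterocyte and colonocyte scores, and neither was tested in a way that separates them. Whether a change of identity in the epithelium alone would lower the HOX 9 to 13 genes this far was not tested.

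The second pattern is a higher score of the Paneth cell and regenerating protein list, here the Paneth score, in colon-like than non-IBD libraries. That list holds REG1A, REG1B, REG3A, REG3G and REG4 beside the defensins, so the score is not a measure of Paneth cells alone. The difference was 1.70 (95% interval 0.53 to 2.78, permutation p = 0.0118, adjusted p = 0.0403 over 84 list and group tests). Those 84 tests include ileum-like comparisons whose small p-values the molecular labels build in, which loosens the adjustment. The colon-like tests were not adjusted on their own, so the score may not pass among them. Ileal tissue carried in these biopsies as a group is argued against. Summed DEFA5 and DEFA6 reached 4.37% of the ileum-like level. The enterocyte genes set beside them were the 17 that lay under 1% of their ileum-like level in non-IBD libraries. Summed, these reached 0.378%, at 84.8 CPM in colon-like and 72.6 in non-IBD libraries. The ratio of the 2 shares was 0.0866 (95% interval 0.023 to 0.314). It was 0.132 (0.0373 to 0.451) without colon-like replicate 4 and 0.0451 (0.0173 to 0.159) without replicate 11. Carried ileal tissue stays open for single libraries, since in 5 of 11 (replicates 1, 2, 5, 7 and 11) the enterocyte share was at least 50% of the defensin share. Defensin shares were 2.97% in replicate 11 and at most 0.471% in the other 4. The number series is argued against too, since the difference was 2.35 within the lower series (exact permutation p = 0.000733). Position along the colon cannot be told apart from disease, because the biopsy site is not in the labels and HOXB13, a marker of the lower colon, had 48.1 ± 59.4 CPM in non-IBD (SD, n = 11) and 5.05 ± 16.2 in colon-like libraries (SD, n = 11; 0.18 ± 0.184 without replicate 5, at 53.7). The difference was 0.85 with HOXB13 as a term (permutation p = 0.213; without colon-like replicate 5 it was 2.03, of which 73.7% remained with that term, p = 0.0464), 0.96 with CLDN8 (p = 0.109) and 1.06 with the HOX score (p = 0.115), so a site difference is a candidate explanation for part of it, beside Paneth cell metaplasia in CD, which was not tested.

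The third pattern is the counts against non-IBD, where for the ileum-like libraries 1 of 100 splits, the real one, gave as many genes (3656, highest other 1155), again no test of chance with molecular labels. For colon-like against non-IBD 100 of 100 splits gave as many as the real 0 (highest other 121), which holds for any count of 0 and decides nothing. For all CD against non-IBD 2 of 100 gave as many as 1519 (highest other 2160), no test of chance either, since the fit rests on the same molecular labels. A difference in depth does not account for most of the all-CD count, since 1142 of the 1519 calls remained in the same direction after thinning, while the test of library size (permutation p = 0.928 for the pooled totals) decided nothing, because it pools subtypes that differ in depth from each other (permutation p = 0.00938), with mean totals below and above non-IBD that did not pass against it (p = 0.258 and 0.425).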
